A study of Homo sapiens with 2 samples.

How the data were processed

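Gene expression was measured in 2 samples of Huh7 cells, 1 with a non-target control hairpin and 1 with a CD24 hairpin, each on 1 Affymetrix array. Total RNA was extracted with Trizol and the label was biotin, per the labels. Probe sets were paired with genes through GEO's annotation of the array platform. The deposited values are log2 values, made with RMA per the submitters' processing notes (robust multi-array average, which corrects the background, quantile-normalises the arrays and summarises the probes of each probe set). The software, its version and the steps after RMA are not given in the sources used here. In the deposited table each probe set was centred on its 2 arrays: the 2 values sum to 0 within 1e-06 on every probe set, each column has a median of 0, and values run from -2.01 to 2.01. The level of a probe set is therefore not in the table, only the difference between the arrays. The log2 scale follows from RMA, and the direction, higher value for more transcript, is borne out by CD24, which is lower in the array labelled CD24 shRNA. No detection calls, scanner files or genome coordinates were used here.

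Of 54675 probe sets, 41091 named 1 gene symbol and were used, 1801 named several and 11777 none here. The 62 control probe sets of the array were left out, 6 of which name ACTB or GAPDH. Of the 41091, the Entrez ID of 41037 was found in the gene table of the reference (GRCh38.p14), which changed 0 symbols. Genes were named from probe sets with 1 symbol, which gave 19775 genes, 9252 of them with 1 probe set. The value of a gene is the mean over its probe sets of the log2 difference, CD24 shRNA minus control. A gene was counted as higher or lower at a 2-fold difference. With 1 array per group no test across samples exists, so no p-value, standard error between cultures or replicate SD was computed. The spread given is the SD over probe sets of a gene, and the pooled within-gene SD over 31839 probe sets of 10523 genes. The number of arrays limits the precision.

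The design fixed before the data were examined assumed that the levels were present, and parts of it could not be carried out. The brightest probe set per gene was replaced by the mean over probe sets, which had been written down as an alternative. The filter on the mean level was dropped. Random lists were matched on the number of probe sets of each gene (4 classes) and on a coarse level class (2 classes) in place of mean expression. The filter at the 75th percentile of level, a second quantile normalisation, the loess trend and the offset of 32 were not run, because each needs the levels. The coarse level class came from the digits of the file. The values are differences of single-precision numbers, whose binary steps become finer below 4 on the log2 scale. Where the digits are exact, a step too fine for a number of 4 or more places the dimmer array below 4. This placed 16218 probe sets below 4; among genes expected to be abundant (ribosomal proteins, EEF1A1, GAPDH, ALB, APOA1 and TTR) it placed 8 of 124 probe sets there, and among olfactory and taste receptor, keratin-associated and defensin genes 102 of 179. A further 3273 probe sets had 0 on both arrays.

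Genes were named by a rule set before the data were examined: CD24, NANOG and STAT3; the 13 largest differences in each direction among genes whose probe sets all have 1 sign; and up to 4 members of each list with the largest difference. HP, FGB, FGG, ALB, APOA1, TTR, FABP1, APOC3, COL1A1, COL1A2, ZYX, PDLIM7, CNN2, CRIM1, AJUBA, CCN2, ITGB1, F9 and C4BPA were named in addition, after their values were seen. The 32 gene lists were written in advance from general knowledge of the tissue and of CD24, and 8 more after the values were seen, for the closing section. For each, the median over measured members was set against 10000 random lists of the same size, drawn without replacement within classes, and a list was said to stand apart below the 2.5th or above the 97.5th percentile. Lists of under 5 measured genes would have been given as values, and the smallest of the 32 had 10. The alternatives tried were other ways to combine probe sets, leaving out probe sets with names ending in _s_at or _x_at, leaving out probe sets placed below 4, centring, scaling on the hybridisation controls, thresholds of 1.5-fold and 3-fold, the mean in place of the median and unmatched random lists.

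The calculations were tested on simulated data for this comparison with 19775 genes, 200 of them changed. At a log2 difference of 1.5 in size 98.0% were recovered at the 2-fold threshold and at a size of 3 all were, and 2 unchanged genes were called. The noise was drawn for each probe set alone, with the pooled within-gene SD, and held no spread between cultures. These rates therefore describe the calculation and give no error rate for the comparison. No simulated probe set was wrongly placed below 4, which follows from the number format. The simulation kept exact binary values, whereas the deposited values were read as decimal text, so it does not test misplacement by rounded digits. The hybridisation control AFFX-r2-P1-cre-5_at was placed below 4. Its values, -0.00160027 and 0.00159931, differ in size by more than numbers below 4 allow. Probe sets called near the background are those placed below 4, so some may be brighter. Of the probe sets simulated below 4 on both arrays, 74.5% were placed there. The share for probe sets below 4 on 1 array only was not computed, so a probe set not placed below 4 may still lie there. Analyses used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.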

Results

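The series addressed which transcripts differ after knockdown of CD24. It compared 2 cultures of Huh7, an established human hepatocellular carcinoma cell line. One culture carried a stable lentiviral short hairpin RNA (shRNA) against CD24, a small cell surface glycoprotein, and the other carried a non-target control hairpin. Total RNA of each was hybridised to 1 Affymetrix array, so each group held 1 array. The table held 54675 probe sets, of which 41091 named 1 gene each, for 19775 genes. The deposited values were log2 values already centred within each probe set, so the 2 values of a probe set were equal and opposite. The quantity reported throughout is their log2 difference, CD24 shRNA minus control. No difference has a replicate check, no p-value was computed, and the number of arrays limits the precision. The error given for a gene is the SD over its probe sets, which covers probe set error on this pair of arrays and not the spread between cultures. The pooled SD between probe sets of 1 gene was 0.27 on the log2 scale (10523 genes with 2 or more probe sets).

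CD24, the target of the hairpin, was lower in the CD24 shRNA array on all 6 of its probe sets. The mean log2 difference was -1.37 ± 0.38 (SD, 6 probe sets), which is 2.58-fold lower, and the probe sets ranged from -1.97 to -0.95. The centred CD24 value was 0.68 in the control array and -0.68 in the CD24 shRNA array. STAT3, a signalling transcription factor, had a log2 difference of 0.33 ± 0.24 (SD, 4 probe sets), with 3 of its probe sets above 0, the highest at 0.57, and 1 at 0. NANOG, a pluripotency transcription factor, had a log2 difference of -0.05 ± 0.07 (SD, 2 probe sets), smaller than the pooled SD between probe sets. All 6 CD24 probe sets have names ending in _s_at or _x_at, which can match more than 1 transcript. The dimmer value of 1 NANOG probe set was placed below a log2 value of 4, near the array's background, and its other probe set was tied between the arrays.

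**Figure D1:**
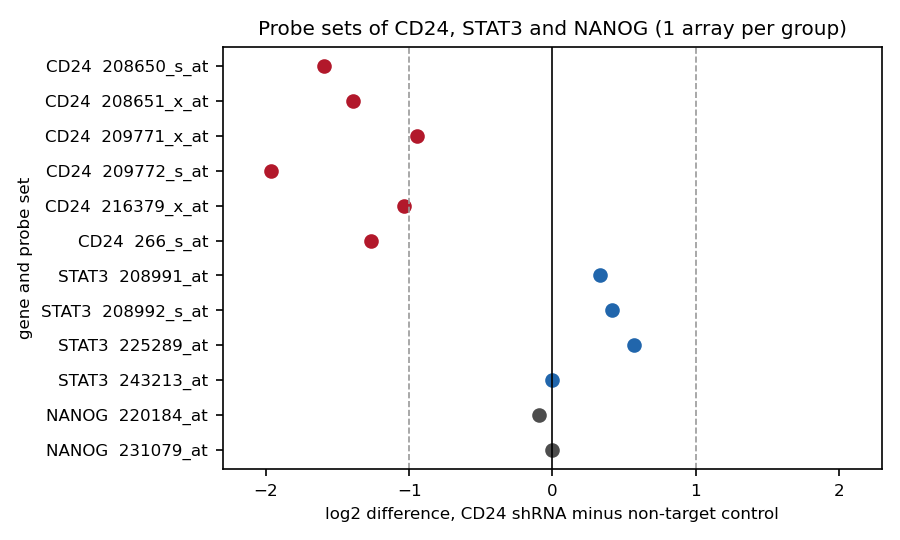
Log2 difference (x axis, CD24 shRNA minus non-target control) of each probe set (y axis) of CD24, STAT3 and NANOG, 1 point per probe set; dashed lines mark 2-fold. The 6 CD24 probe sets lie between -1.97 and -0.95, the STAT3 probe sets between 0 and 0.57 and the NANOG probe sets at -0.10 and 0.

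Across the array, 125 genes were at least 2-fold higher and 96 at least 2-fold lower with CD24 shRNA, together 1.12% of genes, and 22 were over 4-fold higher against 4 over 4-fold lower. With the arrays scaled on their hybridisation controls, which adds 0.11 to every difference, the split was 181 higher and 67 lower. Every probe set lay on the gene's side in 119 of the 125 and in all 96. This holds by definition for the 54 higher and 61 lower genes with 1 probe set. The others were picked by the mean of the same probe sets, so the count is a description only. The 13 largest positive differences among genes whose probe sets all lay on 1 side included several genes of contractile and actin-binding proteins. NPPB, the natriuretic peptide B precursor, was 9.48-fold higher (log2 difference 3.24, 1 probe set). CNN1, the smooth muscle actin-binding protein calponin 1, was 8.48-fold higher (3.08, 1 probe set). KCNJ8, a subunit of ATP-sensitive potassium channels, was 7.73-fold higher (2.95 ± 0.01, SD, 2 probe sets), MYL7, an atrial myosin light chain, 7.36-fold (1 probe set), and NEXN, the F-actin-binding protein nexilin, 5.66-fold (log2 SD 0.50, 2 probe sets). ANKRD1, an ankyrin repeat protein of muscle, was 5.29-fold higher and ACTA1, skeletal muscle alpha-actin, 5.28-fold, each on 1 probe set. TAGLN, the actin-binding protein transgelin, was 6.36-fold higher on average, but its probe sets disagreed, with log2 differences of 4.02 and 3.93 on a pair of them and 0.05 on the third. COL3A1, the type III collagen chain, was 5.09-fold higher on average, with 3 probe sets between 3.41 and 3.78 and the other two at 0.77 and 0.11. Without probe sets with names ending in _s_at or _x_at, TAGLN lay at 0.05 and COL3A1 at 0.44, and 4 of the 5 COL3A1 probe sets and the GPC5 probe set were near the background in the dimmer array. The digits of the file reveal only part of the dim probe sets, so others named here may lie near the background too. Rounded digits can also place a brighter probe set there. Not every such placement is printed for genes with several probe sets. GLIPR1 was 5.08-fold higher on 5 probe sets that agreed (2.34 ± 0.32, SD). PRSS35, a serine protease family member, GPC5, a cell surface heparan sulfate proteoglycan, and LYPD1 completed the 13 largest, at 6.32-fold, 5.38-fold and 5.25-fold, each on 1 probe set.

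The 13 genes with the largest negative differences included several of proteins that the liver secretes. ITIH3, a heavy chain of the inter-alpha-trypsin inhibitor, was 4.18-fold lower, SERPINA3, alpha-1-antichymotrypsin, 3.86-fold, C8B, a chain of complement component C8, 3.53-fold, and FGL1, a liver-secreted fibrinogen-like protein, 3.30-fold. SLC6A14, an amino acid transporter, was the lowest of all at 5.91-fold lower (log2 difference -2.56), followed by DDIT4, a stress-induced inhibitor of mTORC1, at 4.57-fold lower. THBS4, a thrombospondin of the extracellular matrix, was 4.06-fold lower, COL11A1, a fibrillar collagen chain, 3.30-fold (-1.72 ± 1.02, SD, 3 probe sets), and PCOLCE, an enhancer of procollagen processing, 3.23-fold. PLA1A, a phospholipase, was 3.91-fold lower, LGALS14, a galectin, 3.83-fold, TMEM178A 3.38-fold and LAMP5, a lysosome-associated membrane protein family member, 3.24-fold. Apart from COL11A1, these 13 genes were measured by 1 probe set each, as were 8 of the 13 highest. Of 184 genes whose first probe set passed 2-fold and that had other probe sets, the mean of the others had the same sign in 176, or 95.7%, against 61.2% for all genes with several probe sets.

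**Figure D2:**
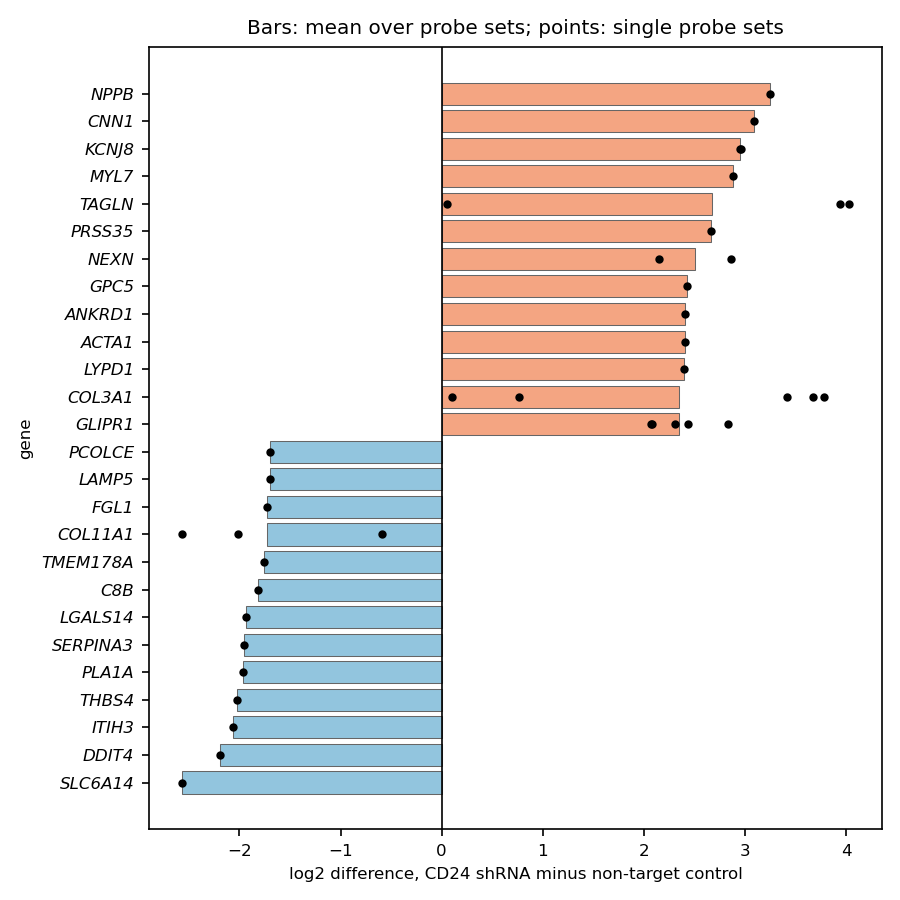
Log2 difference (x axis) of the 13 genes (y axis) with the largest positive and the 13 with the largest negative difference among genes whose probe sets all have 1 sign; bars are means over probe sets and points are single probe sets. NPPB is highest at 3.24 and SLC6A14 lowest at -2.56, and the points of TAGLN and COL3A1 are split between values above 3.4 and values below 0.8.

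Gene lists written before the data were examined were compared with 10000 random lists of the same size, and 13 of 32 lists had a median in the lowest or highest 2.5% of these, against 1.6 expected for unrelated genes. These percentiles describe the 2 arrays: members of a list can vary together, so random genes understate how far a list could move between cultures. Random lists were matched on level only coarsely, so whether their genes were as strongly expressed as the members of each list was not tested. The expected 1.6 is therefore a rough guide. 10 lists lay below and 3 above. The largest shifts below were in NRF2 targets (median log2 difference -0.41), cholesterol synthesis (-0.40), fatty acid synthesis and storage (-0.37) and hypoxia and glycolysis (-0.31), and the largest above was in mesenchymal genes (0.22), with heat shock genes next (0.21). Without probe sets placed below 4, heat shock genes lay higher than mesenchymal genes, at 0.27 against 0.18. The first place of NRF2 targets depends on probe sets with names ending in _s_at or _x_at: without them that list lay at -0.06 and cholesterol synthesis at -0.56. Leaving them out also removed genes with no other probe set, with 17098 of 19775 genes remaining, so lists could lose members.

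**Figure D3:**
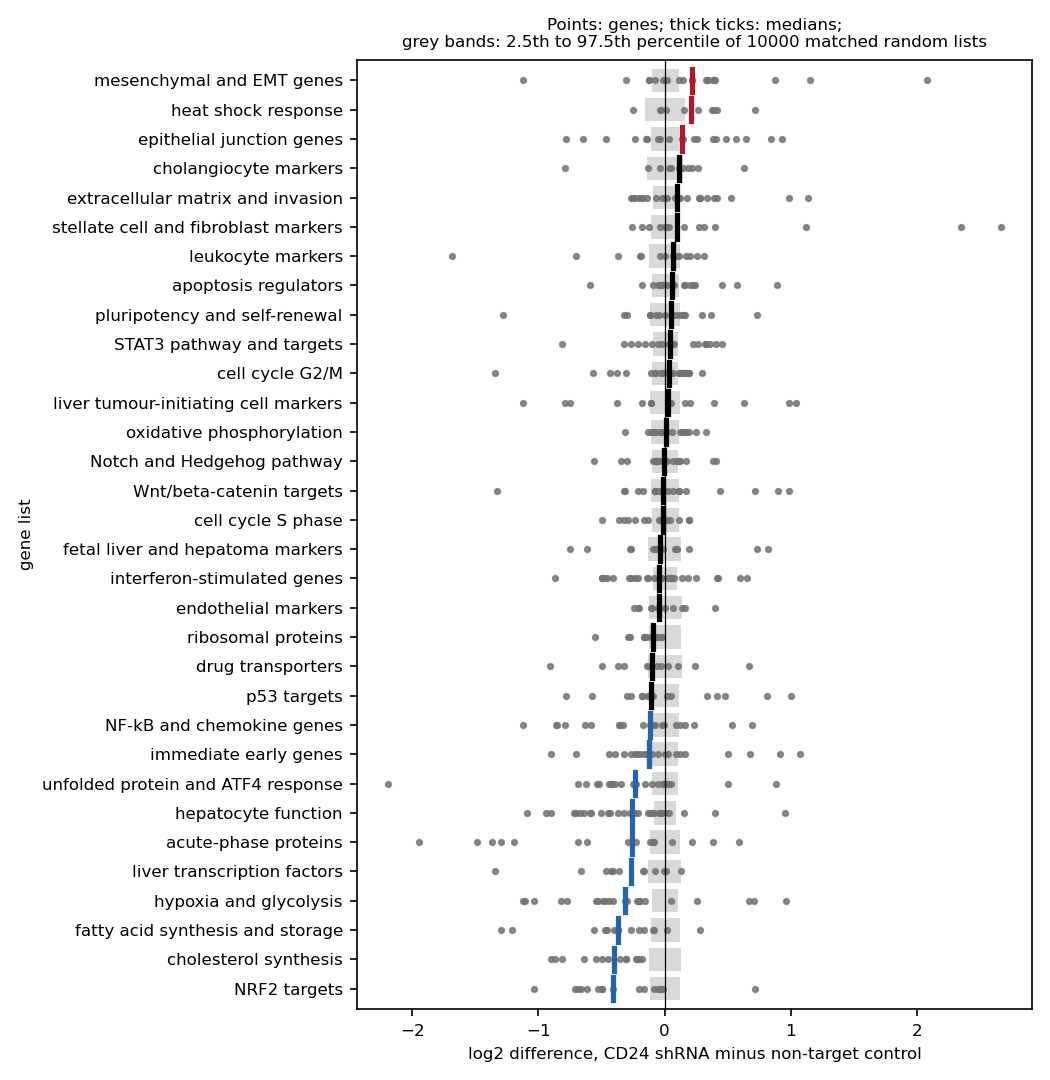
Log2 difference (x axis) of the members of each of the 32 gene lists (y axis), 1 grey point per gene, with the list median as a thick tick (blue in the lowest and red in the highest 2.5% of random lists, black otherwise) and the range of 10000 matched random lists without those tails as a grey band. All 14 cholesterol synthesis genes lie below 0, and the medians run from -0.41 for NRF2 targets to 0.22 for mesenchymal genes.

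Acute-phase, hepatocyte function and liver transcription factor genes were lower as groups. Of 16 measured acute-phase genes, 12 lay below 0 and 5 were at least 2-fold lower, with a median of -0.26 (percentile 0.01). These 5 were SERPINA3, LBP, the lipopolysaccharide-binding protein (2.80-fold lower, log2 difference -1.49 ± 0.33, SD, 2 probe sets), CP, the copper-carrying ceruloplasmin (2.58-fold, -1.37 ± 0.39, SD, 4 probe sets), C3, the central complement component (2.46-fold, 1 probe set), and HP, haptoglobin (2.28-fold, 1 probe set). The fibrinogen chains FGB and FGG went the other way, 1.51-fold higher (0.59 ± 0.02, SD, 2 probe sets) and 1.30-fold higher (1 probe set). Of 30 hepatocyte function genes, 24 lay below 0 and 9 were over 1.5-fold lower (median -0.25, below all random lists). SERPINC1, antithrombin, was 2.13-fold lower (-1.09 ± 0.23, SD, 2 probe sets), AHSG, fetuin-A, 1.92-fold (-0.94 ± 0.13, SD, 2 probe sets) and PCK1, a gluconeogenic enzyme, 1.87-fold, while CPS1, the first enzyme of the urea cycle, was 1.94-fold higher (0.96 ± 0.42, SD, 2 probe sets). Some members moved little or rose: ALB lay at -0.11 ± 0.42 (SD, 4 probe sets), APOA1 at -0.05 ± 0.06 (SD, 3 probe sets) and TTR at 0.40 (1 probe set). Others were lower, among them FABP1 at -0.64 ± 0.04 and APOC3 at -0.67 ± 0.23 (SD, 2 probe sets each). These 5 genes were picked after their values were seen. No levels were available, so abundance was not measured. Of 12 liver transcription factors, 10 lay below 0 (median -0.27, percentile 0.04), with NR0B2, a nuclear receptor that represses bile acid synthesis, 2.53-fold lower and PROX1 1.59-fold lower (-0.67 ± 0.19, SD, 4 probe sets). CEBPA, a hepatocyte transcription factor, had a difference of -0.47 and CEBPB -0.42. Fetal liver and hepatoma markers did not stand apart (14 genes, median -0.04, percentile 25.5): SPINK1 was 1.77-fold and PEG10 1.66-fold higher (0.73 ± 0.39, SD, 2 probe sets), and AKR1B10 1.53-fold lower. DLK1 was 1.68-fold lower on probe sets that differed widely (-0.75 ± 0.75, SD, 2 probe sets, 1 near the background), and lay at -0.22 without probe sets that can match several transcripts.

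Genes of lipid synthesis were lower together. All 14 measured cholesterol synthesis genes lay below 0, none by 2-fold (median -0.40, below all random lists). INSIG1, a sterol-regulated inhibitor of the pathway, was 1.87-fold lower (-0.90 ± 0.38, SD, 3 probe sets), SQLE, squalene epoxidase, 1.83-fold (-0.87 ± 0.31, SD, 4 probe sets), FDPS, farnesyl diphosphate synthase, 1.76-fold and STARD4, a sterol transfer protein, 1.56-fold. Of 16 genes of fatty acid synthesis and storage, 14 lay below 0 (median -0.37, below all random lists). PNPLA3, a lipid droplet protein, was 2.45-fold lower (-1.30 ± 0.07, SD, 2 probe sets) and GPAM, which starts triglyceride synthesis, 2.32-fold lower (-1.21 ± 0.48, SD, 2 probe sets). LPIN1 had a difference of -0.56 ± 0.18 and ELOVL6, a fatty acid elongase, -0.47 ± 0.21 (SD, 3 probe sets each). Without probe sets that can match several transcripts, the fatty acid list had a smaller median of -0.20 (percentile 1.09).

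Several stress and metabolic lists were also lower. Of 23 hypoxia and glycolysis genes, 18 lay below 0 and 3 were at least 2-fold lower (median -0.31, below all random lists). These 3 were PFKFB4, a regulator of glycolysis (2.18-fold lower, -1.12 ± 1.20, SD, 2 probe sets), BNIP3, a mitophagy receptor (2.16-fold, -1.11 ± 0.08, SD, 2 probe sets), and the aldolase ALDOC (2.05-fold). ADM, the vasodilator peptide adrenomedullin, was 1.95-fold higher. Of 17 NRF2 targets, 16 lay below 0 (median -0.41, below all random lists). NQO1, a quinone reductase, was 2.05-fold lower (-1.03 ± 0.13, SD, 3 probe sets), SRXN1, sulfiredoxin, 1.64-fold lower and HMOX1, heme oxygenase, 1.64-fold higher. The cystine transporter gene SLC7A11 was 1.61-fold lower on average (-0.68 ± 0.79, SD, 3 probe sets), with 1 probe set above 0, and lay at -1.14 without probe sets that can match several transcripts. Without probe sets that can match several transcripts, the NRF2 list had a median of -0.06 (percentile 19.95), within the random range. That list then held fewer members, with NQO1 among those lost, so the medians cover different sets of genes. Of 23 genes of the unfolded protein and ATF4 response, 18 lay below 0 (median -0.23, below all random lists), led by DDIT4, with TRIB3, a pseudokinase, 1.54-fold lower (-0.62 ± 0.09, SD, 2 probe sets) and VLDLR 1.85-fold higher. Of 21 NF-kB and chemokine genes, 15 lay below 0 (median -0.11, percentile 2.095). The adhesion molecule ICAM1 was 2.18-fold lower (-1.12 ± 0.18, SD, 3 probe sets), and CCL20, LCN2 and CXCL10 were 1.82-fold, 1.81-fold and 1.73-fold lower. Immediate early genes had a median of -0.13 (percentile 0.66) with members on both sides. DUSP4, a MAP kinase phosphatase, was 2.11-fold higher (1.07 ± 0.19, SD, 3 probe sets), PHLDA1 1.89-fold higher (0.92 ± 0.61, SD, 6 probe sets), EGR1 1.87-fold lower (-0.90 ± 0.62, SD, 3 probe sets, 2 near the background) and ETV4 1.62-fold lower (-0.70 ± 0.10, SD, 2 probe sets). The mean of the list lay within the random range (percentile 29.8). Without probe sets that can match several transcripts, the NF-kB and immediate early lists lay within the random range (percentiles 6.57 and 4.76), although their medians hardly moved, both to -0.11. Both lists lost members in that setting, ICAM1 and EGR1 among them, and shorter lists have wider random ranges.

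Mesenchymal genes were higher as a group: 14 of 21 lay above 0 (median 0.22, percentile 99.98). CCN1, a matricellular protein, was 4.23-fold higher (log2 difference 2.08 ± 0.30, SD, 2 probe sets), CDH2, N-cadherin, 2.23-fold (1.16 ± 0.30, SD, 2 probe sets) and VIM, vimentin, 1.83-fold (0.88 ± 0.25, SD, 2 probe sets), whereas S100A4, a calcium-binding protein, was 2.17-fold lower. Beside this shift, TAGLN and COL3A1 also belong to the stellate cell and fibroblast markers, whose median was 0.10 (14 genes, percentile 94.3). That call depends on the method: the mean of the list was 0.48 (percentile 100), and its median 0.15 (percentile 99.3) with the median over probe sets and 0.31 (percentile 98.6) with the largest probe set per gene. LUM, lumican, was 2.18-fold higher on probe sets near the background that differed widely (1.12 ± 1.41, SD, 2 probe sets), at 2.12 and 0.13. COL1A1 lay at -0.13 ± 0.30 (SD, 5 probe sets) and COL1A2 at 0.28 ± 0.20 (SD, 3 probe sets). Of 20 epithelial junction genes, 12 lay above 0 (median 0.14, percentile 99.3). The keratins KRT8 and KRT18 were 1.90-fold and 1.80-fold higher. CDH1, E-cadherin, was 1.72-fold lower (-0.78 ± 0.32, SD, 2 probe sets, 1 near the background) and ESRP1, an epithelial splicing factor, 1.57-fold lower. The heat shock list was also above the random range (10 genes, median 0.21, percentile 99.4), with HMOX1 followed by DNAJB1, CRYAB and BAG3 at 0.42, 0.39 and 0.38. The epithelial and heat shock lists returned to the random range without probe sets that can match several transcripts (percentiles 91.7 and 92.8), with smaller medians of 0.10 and 0.14. KRT8, KRT18, CDH1, DNAJB1 and BAG3 had no value in that setting, so the lists were shorter. Extracellular matrix and invasion genes did not stand apart by the median (24 genes, 0.10, percentile 96.5) but did by the mean (0.15, percentile 98.8), and the metalloproteinase inhibitors TIMP2 and TIMP3 were 2.20-fold and 1.98-fold higher (1.14 ± 0.30, SD, 3 probe sets, and 0.98 ± 0.63, SD, 4 probe sets), and LAMB1 and PLAU lay at 0.53 and 0.42.

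Lists tied to liver tumour-initiating cells and self-renewal did not stand apart as groups. Of 16 tumour-initiating cell markers, 9 lay above and 7 below 0 (median 0.03, percentile 68.2). PROM1, which encodes the surface marker CD133, was 2.06-fold higher on 1 probe set. LGR5, a Wnt-associated receptor, was 1.98-fold higher (0.99 ± 0.19, SD, 2 probe sets, 1 near the background). ICAM1 was 2.18-fold and SOX9 1.73-fold lower (-0.79 ± 0.15, SD, 2 probe sets). Of 17 pluripotency and self-renewal genes, 9 lay above and 7 below 0 (median 0.05, percentile 77.6), with LEFTY1, an inhibitor of Nodal signalling, 2.44-fold lower and LIN28B, an RNA-binding repressor of let-7, 1.66-fold higher, each on 1 probe set. PRDM14 lay at 0.37 and MYC at -0.33. POU5F1, BMI1 and TDGF1 of the self-renewal list had no value here, so its median does not cover them. Of 20 genes of the STAT3 pathway and its targets, 12 lay above and 8 below 0 (median 0.04, percentile 74.4, or 0.27 and 98.35 with the largest probe set per gene). IL6R, the interleukin-6 receptor, was 1.76-fold lower (-0.81 ± 0.62, SD, 3 probe sets, 1 near the background). MCL1 lay at 0.45 ± 0.30 (6 probe sets, 3 near the background), CEBPD at 0.40 ± 0.34 (2 probe sets) and JAK1 at 0.36 ± 0.35 (5 probe sets). Wnt targets (19 genes, median -0.01, percentile 35.8) held ZNRF3, a Wnt receptor ubiquitin ligase, at 2.51-fold lower, SP5 at 1.86-fold higher and TNFRSF19 at 1.64-fold higher (0.71 ± 0.52, SD, 3 probe sets, 2 near the background). Notch and Hedgehog genes had a median of -0.01 (21 genes, percentile 38.3), the largest being NRARP at -0.56. Drug transporters had a median of -0.10 (13 genes, percentile 5.61), with ABCB4 1.87-fold lower (-0.91 ± 0.24, SD, 2 probe sets) and ABCB1, the multidrug efflux pump, 1.59-fold higher (0.67 ± 0.26, SD, 2 probe sets).

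Proliferation, death and housekeeping lists lay within the random range. S phase genes had a median of -0.02 (20 genes, percentile 33.8) with none beyond 1.5-fold. G2/M genes had a median of 0.04 (25 genes, percentile 75.1) with 1 beyond 1.5-fold, HMMR, a hyaluronan and spindle-associated protein, at 2.54-fold lower (-1.34 ± 0.05, SD, 2 probe sets). The p53 targets had a median of -0.11 (17 genes, percentile 2.81), with GADD45A at 1.00, TIGAR 1.75-fold higher, SFN 1.72-fold lower (-0.78 ± 0.14, SD, 3 probe sets) and CDKN1A, a cell cycle inhibitor, at -0.57. Their mean was of opposite sign at 0.02, and with the largest probe set per gene their median was -0.35 (percentile 0.14). Apoptosis regulators had a median of 0.06 (19 genes, percentile 83.9), led by BIK at 1.85-fold higher and BMF at -0.59. Oxidative phosphorylation genes had a median of 0.01 (18 genes, percentile 53.3). All 16 ribosomal protein genes lay below 0, by little (median -0.09, percentile 5.65), and this sign turned when the arrays were scaled on the hybridisation controls (median 0.02), as did the sign of every other list median between 0 and -0.11 except that of the NF-kB list. The median and mean also differed in sign for the pluripotency (mean -0.01), G2/M (mean -0.06), Wnt (mean 0.05) and leukocyte (mean -0.12) lists.

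Endothelial, leukocyte and cholangiocyte markers and genes of a response to double-stranded RNA did not stand apart either. Interferon-stimulated genes had a median of -0.04 (30 genes, percentile 16.5). IFIT5 was 1.82-fold lower (-0.87 ± 0.26, SD, 2 probe sets, 1 near the background), ISG15 1.51-fold higher and PSMB9 1.57-fold higher on a probe set near the background. Endothelial markers had a median of -0.04 (12 genes, percentile 23.45), leukocyte markers of 0.07 (15 genes, percentile 87.4) and cholangiocyte markers of 0.11 (11 genes, percentile 93.6). Without probe sets that can match several transcripts, the cholangiocyte median was 0.22 (percentile 99.1), above the random range. Single members did differ: LYZ, lysozyme, was 3.21-fold lower (-1.68 ± 0.15, SD, 2 probe sets) and TYROBP 1.63-fold lower on a probe set near the background. KRT19, a biliary keratin, was 1.55-fold higher (0.63 ± 0.34, SD, 2 probe sets, 1 near the background). Among the array's own controls, the 18 hybridisation control probe sets had a median difference of -0.11, between -0.23 and 0.08, and the 27 poly-A control probe sets a median of -0.20, between -0.50 and 0.39. The control probe sets of GAPDH differed by -0.28 at the 5′ end and -0.19 at the 3′ end, and those of ACTB by 1.19 at the 5′ end and 0.44 at the 3′ end.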

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

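Among 11721 probe sets without a gene symbol here, control probe sets left out, which entered no comparison, 31 were at least 2-fold higher and 65 at least 2-fold lower with CD24 shRNA. The largest positive difference among them was 2.02. The test of RNA integrity in the next paragraph was chosen after its result was seen.

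The 5′ control probe set of ACTB, outside the gene comparison, had a log2 difference of 1.19, against 0.65 in the middle and 0.44 at the 3′ end of the transcript, a shift of 0.76 from the 3′ to the 5′ end. One technical explanation is a difference in RNA integrity between the arrays. GAPDH, whose control probe sets are read the same way, had a shift of -0.095 and the 2 pairs for ribosomal RNA 0.10 and -0.31 (3′ end near the background), so none of these shifted like ACTB. The 9 pairs of poly-A control probe sets, which read added transcripts and not cell RNA, had shifts from -0.37 to 0.60 (SD 0.37), so against that spread these values cannot exclude the explanation, and single transcripts can shift without it. That SD is rough: most of these pairs read the same added transcript as another pair. The 5′ ends of the ThrX and TrpnX pairs were also near the background. The ACTB gene itself was 1.35-fold higher over its 3 other probe sets (0.44 ± 0.01, SD), so a change of the transcript, or of what else the 5′ probes match, may contribute and was not tested.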

How the results depend on the processing

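No replicate could be left out, and no test across samples exists, because each group held 1 array. The counts of genes depend on how probe sets are combined and on the threshold. Against 125 higher and 96 lower genes, taking the probe set with the largest absolute difference gave 303 and 209 (and a CD24 difference of -1.97), a 1.5-fold threshold 521 and 470, and a 3-fold threshold 32 and 17; the larger counts follow from picking the extreme probe set and the looser threshold. The other alternatives gave 99 to 181 higher and 67 to 105 lower genes. Scaling on the hybridisation controls, chosen after seeing the data like the median over probe sets, the largest probe set and the removal of low-level probe sets, moved the median of all genes by 0.11 and the split to 181 higher and 67 lower. CD24 stayed between -1.97 and -1.26 where it had a value; with _s_at and _x_at probe sets left out it had none. Between 9 and 14 lists stood apart under every alternative, against 13. Leaving out _s_at and _x_at probe sets left 17098 of 19775 genes, so lists could lose members as well as probe sets. It took the NRF2 median from -0.41 to -0.06 and ended its call. It also ended the calls for the NF-kB (median -0.11 in both) and immediate early (-0.13 to -0.11) lists, which hardly moved, and for the epithelial junction (0.14 to 0.10) and heat shock (0.21 to 0.14) lists. The epithelial junction and immediate early calls also ended with the largest probe set and with the mean in place of the median, and the immediate early call without low-level probe sets. The cholangiocyte, stellate, extracellular matrix, p53 and STAT3 pathway lists stood apart under some alternatives only. The acute-phase, hepatocyte function, liver transcription factor, cholesterol, fatty acid, hypoxia, unfolded protein and mesenchymal lists kept theirs under each alternative that could change them. TAGLN and COL3A1 depend on the probe set: without _s_at and _x_at probe sets they lay at 0.05 and 0.44, and at the median over probe sets at 3.93 and 3.41. Centring each array on its median moved nothing, since both medians were 0, and scaling on the hybridisation controls adds the same number to every gene, so neither tests the calls of lists. The level filters, the repeated quantile normalisation, the loess trend and the offset were not run, because the table holds no levels. Near the background, where the dimmer array lay below 4, a fold understates the change. Leaving out the probe sets placed there, which may be only part of them and may include brighter ones, gave 132 higher and 105 lower genes.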

Other observations

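The lists new to this part were written after the largest differences had been seen, and the tests of fibroblast markers, of STAT3 and of the hepatocyte list were chosen after their results were seen, as was leaving ITGB1 and CCN2 out of the SRF and YAP targets. Metallothioneins, small metal-binding proteins, were higher as a family: 8 of 9 measured genes lay above 0 and 7 were over 1.5-fold higher, with a median of 0.95. MT1M was 2.36-fold, MT1F 2.21-fold and MT1X 2.19-fold higher, and probes of these near-identical genes can read each other's transcripts. Annexins did not move together: ANXA3 and ANXA1 were 4.50-fold and 4.44-fold higher (ANXA1 log2 SD 1.66, 2 probe sets), and the other 9 measured annexins lay between -0.27 and 0.17. Among 13 tubulins, 11 lay above 0 (median 0.18), with TUBB6 2.39-fold and TUBA1A 1.87-fold higher. Collagens went both ways (30 genes, median 0.01), with COL3A1 higher, and COL11A1 and COL9A3 lower by 3.30-fold and 3.18-fold.

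Complement and coagulation genes were also lower at the median. Of 18 complement genes, 16 lay below 0 (median -0.38), with C8B, C8A and C3 3.53-fold, 2.61-fold and 2.46-fold lower and C1R 1.90-fold lower. Of 16 coagulation genes, 13 lay below 0 (median -0.32), with PLG, plasminogen, 2.24-fold lower (-1.17 ± 0.22, SD, 3 probe sets) and F13B, a factor XIII subunit, at -0.75. SERPINC1, F2 and F9 (at 0) in this list are also hepatocyte function genes, as C3 and C4BPA (at 0.22) are acute-phase genes. The medians of these lists were not computed without the shared genes.

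The contractile genes and COL3A1 among the largest positive differences could come from fibroblasts or stellate cells among the CD24 shRNA cells. The other 12 markers of that list had a median of 0.028 and a 75th percentile of 0.29 (at most 0.40 under each alternative), with the abundant fibroblast collagens COL1A1 and COL1A2 at -0.13 and 0.28 and no probe set of either above 0.43, which argues against that source, although LUM, lumican, lay at 1.12 ± 1.41 (SD, 2 probe sets, both near the background). A hypothesis is that targets of SRF and its cofactor MRTF were higher: the 20 targets other than the 7 noticed first had a median of 0.58, at percentile 100 of matched random lists (0.66, percentile 100, without ITGB1, which was in an earlier list), among them ZYX 2.12-fold, PDLIM7 1.90-fold and CNN2 1.86-fold higher. The 17 YAP and TAZ targets other than the 4 noticed first also lay high, with a median of 0.37 at percentile 100 (16 targets, 0.37, percentile 100, without CCN2, which was in an earlier list at 0.22), among them CRIM1 1.84-fold and AJUBA 1.66-fold higher. Both programmes respond to cell shape and density, and with 1 array per group an effect of the CD24 hairpin, an off-target effect of it and a difference between the 2 cultures other than CD24 cannot be told apart.

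The lower acute-phase genes might follow from less STAT3 transcript, but STAT3 had a difference of 0.33, above 0 on every probe set that differed, so the tables argue against that. STAT3 activity was not measured. A broader decrease of hepatocyte expression stays open, as does a difference between the cultures: the 30 hepatocyte function genes had a median of -0.25, at percentile 0 of matched random lists, but none of them is in the acute-phase list, so leaving out acute-phase genes changed nothing and tested nothing.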
